A study of Platichthys stellatus with 16 samples.

How the data were processed

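The values came from 1 table of 16270 assembled genes, which per the file headers holds for each library an expected count and an FPKM. The identifiers are of the form written by the Trinity assembler. The authors estimated the counts with RSEM, per the deposited processing notes. The versions of the assembler, the aligner and RSEM are not given in the sources used here, and neither is the strand setting. Per the labels, RNA was extracted with Trizol from 3-year-old fish, checked on an Agilent instrument and sequenced on an Illumina HiSeq. The extraction protocol describes 24 libraries. The 16 listed samples, 2 per sex and tissue, were matched to their columns by sex, tissue and replicate number. A further 16 value columns of the table belong to no listed sample, and they were not used here. No reference genome and no raw reads were used here.

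The expected counts were read as RSEM estimates, since they hold fractions: in the library with the fewest, 94.12% of values were exactly whole as printed in the table, with at most 2 decimals. The table does not hold every count of a library. Total fragments per library were recovered from the ratio of count to FPKM, over genes whose effective length equals their length less a fixed offset (240 to 285 bases). The recovered total was taken at the peak of that ratio, in bins of 0.8% that held 313 to 1638 genes. It came to 9626209 to 16584847, to within that bin width, so the table lists 51.4 to 80.8% of the counts of a library. In a test with 3 simulated totals the recovered value was off by at most 0.073%. A fold from counts can differ from a ratio of FPKM, because FPKM divides by the effective length of the isoforms in each library and by the recovered total, while the fold from counts uses TMM scaling. No gene was removed, since the filter chosen (1 FPKM in at least 2 libraries) was met by each of the 16270. Of these, 724 had under 3 counts in at least 1 library.

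Each comparison was tested in edgeR by the quasi-likelihood F test, two-sided, on expected counts rounded to whole numbers, with TMM scaling (factors 0.623 to 1.845). The fit gave a mean to each of the 8 groups over the 16 libraries, with 8 residual degrees of freedom and a median biological coefficient of variation of 0.37. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The choices made before the data were examined took the values to be RPKM, to be tested by limma on log2(RPKM + 1). The table held counts, so edgeR took the place of limma, and limma on log2(FPKM + 1) became an alternative. The comparisons, the threshold, the gene lists and the rule for naming genes were fixed before the data were examined.

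The comparisons were each tissue against each of the other 3 as an average over sexes, female against male within each tissue, the average of the sex difference over brain, liver and muscle, the sex difference in gonad against that average, and the sex difference in liver against the mean of brain and muscle. A feature was tissue-enriched with an adjusted p below 0.05 and a log2 difference of at least 2 over each of the other 3 tissues. Libraries of different tissues may come from the same fish, and the edgeR fit treats them as independent.

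Names are those of the closest Swiss-Prot protein or KEGG ortholog in the authors' annotation, and 11450 features carry 7970 distinct names. Where several features share a name, the one with the highest mean stands for it. Genes were named by rule: for each comparison, members of the gene lists past the threshold, up to 20 by size of the difference, and the 5 named features with the largest increase and the 5 with the largest decrease among those past the threshold whose groups did not overlap. Tissue-enriched features were ranked by the smallest of the 3 differences. Some genes that meet the rule are not reported here. Levels are the authors' FPKM. The share of mitochondrial genes is over the 11 features named as encoded in mitochondrial DNA.

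The lists, with symbols in the list, symbols matched and features, were: growth hormone and IGF axis (48, 5, 9), brain-pituitary-gonad axis (33, 2, 4), steroid hormone synthesis (30, 10, 12), liver vitellogenesis and eggshell proteins (21, 1, 1), oocyte and ovary (30, 0, 0), testis and sperm (58, 6, 6), hepatocyte (42, 8, 12), skeletal muscle (50, 8, 11), neuron and glia (45, 4, 4), pituitary hormones (15, 0, 0), exocrine pancreas (21, 1, 1), blood cells (18, 3, 3), immune cells (20, 3, 4) and sex determination (22, 1, 5). The 6 lists with at least 5 features were tested as sets by camera with a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Of 15 set results past the threshold with the preset value, 2 passed with the estimated one: hepatocyte genes in liver and skeletal muscle genes in muscle. In addition 438 Gene Ontology terms of 10 to 500 genes were tested, a choice made after the data were seen.

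The 2 libraries of a group were more different than counting noise allows in each of the 8 groups (chi-square over degrees of freedom 32.1 to 135.3, log2 correlation 0.851 to 0.958). Counts were simulated independently for each library, with 1 spread per gene, estimated from these libraries and shared by the 8 groups. In them the edgeR test in brain recovered 1.5% of planted 2-fold, 38.8% of 4-fold and 80.3% of 8-fold differences. It made 4 calls among features with no planted difference. The average over 3 tissues recovered 26.9%, 89.6% and 100%, with 9 such calls. With no planted difference, 2 features were called in liver and 0 by edgeR in the liver interaction. The simulation left out unequal spread between groups and the departure of female liver 1 described below, so it may understate such calls in these data. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.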

Results

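RNA-seq libraries were made from brain, liver, gonad and muscle of 3-year-old female and male starry flounder (Platichthys stellatus), a flatfish of North Pacific coasts. The sample labels name muscle where the series text names pituitary, and the sample labels were followed. The 8 groups, each 1 sex and 1 tissue, held 2 libraries each, 16 in all. Expression was measured over 16270 genes assembled from the reads, of which 11450 (70.4%) carried a gene name from their closest annotated protein. The total of estimated counts per library ran from 5134221 in female muscle 2 to 12972574 in male gonad 2. Each gene in the table stood at 0.31 FPKM or more in each of the 16 libraries, so genes silent in one sex or one tissue are outside the comparisons. FPKM values below are means ± SD of the 2 libraries of a group (n = 2). Log2 differences are female minus male, or the named tissue minus another, ± SE. The SE is the absolute log2 difference over the square root of edgeR's quasi-likelihood F on 16 libraries, so it restates that test. Adjusted p-values are edgeR's with Benjamini-Hochberg adjustment. The labels do not give the fish behind each library, so the p-values measure the spread between these samples. Gene symbols name the closest known protein, and a feature may be a fragment or one of several close copies of a gene. Where differences are called the largest, only named features past the threshold were ranked. Outside the interactions, their groups also did not overlap.

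The first comparison asked which genes marked each tissue as an average over both sexes. Liver was marked by plasma proteins. VMO1 (TRINITY_DN124168_c0_g1), a homolog of an egg membrane protein, stood at 18100 ± 4340 FPKM in female and 36800 ± 2610 in male liver, a log2 difference of 12.63 ± 1.04 over muscle, the nearest tissue (adjusted p = 1.1e-06). Hemopexin (hpx), which binds free heme in plasma, was higher by 12 ± 0.95 (adjusted p = 8.2e-07) and complement C3 by 11.95 ± 0.94 (7.3e-07). Transferrin, plasminogen and the fibrinogen chains FGA and FGB exceeded their nearest tissue by 9.85 to 10.65. The yolk precursor gene vtg1 was higher in liver than in brain, its nearest tissue, by 4.34 ± 0.47 (1.3e-05), as an average over both sexes. That average came from females, since in males vtg1 stood lower in liver than in brain, at 144 ± 34 against 498 ± 107 FPKM. Of the 12 features of the hepatocyte list, 10 were higher in liver than in the average of the other tissues and 0 were lower, and the count was the same adjusted over the list alone. In edgeR the 2 others, both annotated as FBP1, did not differ at an unadjusted p of 0.05 either. The list rose as a set in liver (camera adjusted p = 4.35e-33, and adjusted p = 0.00133 with an estimated correlation).

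Among the features most enriched in muscle were actins, a tropomyosin and glycolytic enzymes. Aldoa, the muscle form of aldolase, stood at 101000 ± 20100 FPKM in female and 16900 ± 6450 in male muscle, 11.19 ± 1.1 above liver (adjusted p = 5.9e-06). TPM3, annotated as tropomyosin, was higher by 8.9 ± 0.88 (6.3e-06), Actg2, an actin, by 7.56 ± 0.53 (6e-07), beta-enolase ENO3 by 7.25 ± 0.89 (2.7e-05) and skeletal actin ACTA1 by 7.08 ± 0.69 (5.6e-06). The heat shock cognates hsc71 and hspa8, neighbouring features of 1 assembled cluster, were higher by 8.47 ± 1.12 and 8.15 ± 0.96. PFKM, the muscle type of phosphofructokinase, was instead enriched in brain (3.3 ± 0.52, 0.00017). Of the 11 features of the skeletal muscle list, 9 were higher and 1 was lower in muscle, and 9 were higher and 2 lower adjusted over the list alone. The list rose as a set (camera adjusted p = 4.86e-13, and adjusted p = 0.00684 with an estimated correlation).

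Among the features most enriched in gonad were 3 that act in DNA replication. The replication licensing factor mcm2 stood at 156 ± 53.7 FPKM in female and 336 ± 46.8 in male gonad, 6.27 ± 0.48 above brain (adjusted p = 1.3e-06). The primase subunit PRIM1, at 118 ± 6.7 and 40.6 ± 0.509, was higher by 5.17 ± 0.29 (5.4e-07), and rrm2, which makes deoxyribonucleotides, by 5.82 ± 0.45 (1.3e-06). The kinase PIM3 was higher by 6.36 ± 0.44 (8.1e-07). From the testis and sperm list, odf3, a protein of the sperm tail, was higher by 3.59 ± 0.32 (2.8e-06) and stood at 52.2 ± 1.14 FPKM in female and 49.1 ± 1.76 in male gonad. Of the 6 features of that list, 3 were higher and 1 was lower in gonad, also adjusted over the list alone. As a set it did not pass (camera adjusted p = 0.0789). Only 6 of its 58 symbols were matched, and genes silent in another tissue are outside the table. Brain was marked by gja1, a gap junction protein (5.86 ± 0.46 above muscle, adjusted p = 1.3e-06), by GNG13, a G protein subunit (5.84 ± 0.48, 2.3e-06), and by MBP, the myelin basic protein (5.59 ± 0.41, 9.9e-07). The aromatase gene cyp19a1, which makes estrogen from androgen, was higher in brain by 4.72 ± 0.93 (0.00099). Its level was 192 ± 244 FPKM in female and 67.9 ± 91.9 in male brain, so its SD exceeded its mean in both sexes.

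A feature counted as enriched in a tissue when edgeR's adjusted p was below 0.05 and the log2 difference at least 2 against each of the other 3 tissues. By this rule 288 features were enriched in brain, 508 in liver, 389 in gonad and 304 in muscle. Applied within each sex separately, the rule was met in both sexes by 105 features in brain, 266 in liver, 98 in gonad and 148 in muscle. With libraries scaled by their recovered total counts, in place of TMM, the counts were 222 in liver, 1554 in gonad and 156 in muscle.

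The other lists were compared over tissues in the same way. In brain 12 of 12 hepatocyte features were lower than in the average of the other tissues (camera adjusted p = 3.71e-06, but adjusted p = 0.0915 with an estimated correlation). In muscle 12 of 12 were lower (adjusted p = 1.67e-08, but adjusted p = 0.076 with an estimated correlation). In gonad 10 of 12 were lower and 2 higher (adjusted p = 0.00397, but adjusted p = 0.259 with an estimated correlation). Skeletal muscle features were lower in gonad for 8 of 11, or 9 adjusted over the list alone (0.00253, but adjusted p = 0.145 with an estimated correlation), and in liver 7 were lower and 1 higher (0.00659, but adjusted p = 0.164 with an estimated correlation). The sex determination list had 5 matched features, each annotated as beta-catenin, a protein of cell adhesion and Wnt signalling. All 5 were higher in brain (0.000358, but adjusted p = 0.0813 with an estimated correlation) and 5 of 5 were lower in muscle (0.00405, but adjusted p = 0.0766 with an estimated correlation). Apart from the 9 in gonad, each count was the same adjusted over the list alone.

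Of the 9 features of the growth hormone and IGF axis, 6 were higher in liver (camera adjusted p = 0.0408, but adjusted p = 0.166 with an estimated correlation) and 7 were lower in gonad (0.0107, but adjusted p = 0.145 with an estimated correlation). Of the 12 steroid synthesis features, 7 were higher and 2 lower in liver (0.0408, but adjusted p = 0.164 with an estimated correlation). Among lists too small for a set test, 4 of 4 features of the brain-pituitary-gonad axis were higher in liver. Of the 4 neuron and glia features, only MBP was higher in brain, and ENO2 was enriched in muscle by 5.96 ± 0.76 (4.7e-05). ENO2 is the name of the neuronal enolase, but the feature neighbours one annotated as the beta-enolase ENO3 in 1 assembled cluster. Its place among neuron genes rests on its name alone. The counts over these lists were the same adjusted over the list alone. The chymotrypsin-like protease CTRL, the 1 feature of the exocrine pancreas list, was enriched in liver by 2.66 ± 0.54 (9e-04). LCP1, in the immune list by its symbol, is annotated as a digestive cysteine proteinase and was higher in liver by 7.66 ± 1.73 (0.0019). No feature matched the lists of oocyte and ovary genes and of pituitary hormones. Genes silent in any of the 16 libraries are outside the table, so this absence does not show a lack of expression.

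The sexes were then compared within each tissue, beginning with the gonad. Among named features the largest difference was in MAP1LC3C (TRINITY_DN148239_c3_g2), a protein of the autophagosome membrane. It stood at 1510 ± 312 FPKM in female and 9.16 ± 8.74 in male gonad (log2 difference 9.81 ± 0.86, adjusted p = 1.4e-05). Thap4 stood at 5510 ± 1030 against 58.2 ± 22.7 (7.18 ± 0.45, 4.7e-06), and CD9, a tetraspanin that eggs need for fusion with sperm in mammals, at 208 ± 11.4 against 2.86 ± 1.1 (6.81 ± 0.66, 2.3e-05). The transporter subunit slc51a and the heparan sulfate enzyme HS3ST1 were higher in females by 7.97 ± 0.85 and 6.81 ± 0.48. In the male gonad ERVV-2, an endogenous retrovirus envelope gene, stood at 968 ± 406 FPKM against 3.16 ± 0.94 in females (-7.54 ± 0.59, 1.1e-05), and the clock gene PER1 at 138 ± 8.39 against 0.945 ± 0.318 (-6.82 ± 0.67, 2.5e-05).

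Some features of the steroid and growth lists differed between the gonads as well. Hsd3b7, annotated as 3 beta-hydroxysteroid dehydrogenase type 7, was higher in female gonad (45.8 ± 11.4 against 8.94 ± 2.86 FPKM, 3.36 ± 0.63, adjusted p = 0.00095). The steroid hydroxylase cyp17a1, at the branch to sex steroids, was higher in females by 1.59 ± 0.42 (0.0071), a call that ended without male gonad 2 (adjusted p = 0.088) and under scaling by recovered totals. Of the 4 brain-pituitary-gonad features 2 were higher in males. Of the 9 growth hormone and IGF features, 7 were higher in males and 1, IGFBP5, which binds insulin-like growth factors, was higher in females (2.87 ± 0.56, 0.0013). Those higher in males included JAK2, a kinase that signals from the growth hormone receptor (-1.54 ± 0.36, 0.0033). As a set the list did not pass (camera adjusted p = 0.102). The steroid list had 4 features higher in females and 1 higher in males of 12 and did not pass as a set (0.823), and the testis and sperm list had 1 of 6 higher in females (0.996). Each of these counts was the same adjusted over the list alone. Genes silent in one sex or one tissue are outside the table, so the testis and sperm result covers only the 6 matched features.

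Some lists brought in other cell types. CD74 and ptprc, genes of antigen presentation and of leukocytes, were higher in male gonad by -4.18 ± 1.06 (adjusted p = 0.0059) and -3.67 ± 1.07 (0.012) as female minus male. They were the 2 of 4 immune features that passed. Neither passed without male gonad 2 (0.1 and 0.22) or without female gonad 1 (0.057 and 0.092). Of the 4 neuron and glia features 3 were higher in males (none passed without male gonad 2, Mag at 0.55 and slc17a7 and MBP at 0.1, or without female gonad 1, at 0.15, 0.16 and 0.068, and Mag and MBP did not pass without female gonad 2, at 0.087 and 0.093), of the 12 hepatocyte features 4 were higher in females and 1 in males, and of the 5 beta-catenin features 3 were higher in females (camera adjusted p = 0.102 for that list), each the same adjusted over the list alone. CTRL was higher in females by 1.98 ± 0.75 (0.042), a call that ended with any of the 4 gonad libraries left out (0.085 to 0.17). By edgeR 0 of 3 blood features and 0 of 11 skeletal muscle features passed (0 and 3 at an unadjusted p below 0.05). The yolk precursor gene vtg1 was lower in female than in male gonad, at 44.4 ± 18.8 against 408 ± 108 FPKM (-4.37 ± 0.69, 0.00031). The counts behind it were 25 and 26 in the female and 1030 and 857 in the male libraries, and the effective length implied by count and FPKM was 58 and 31 bases in females and 146 and 156 in males, for a gene of 944 bases.

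In the gonad 7661 features differed, 3795 higher in females and 3866 higher in males. Scaled by recovered totals the split was 1881 and 5670. That scaling moved the median log2 sex difference of all genes from -0.03 to -0.73 in gonad, from 0.13 to -0.46 in brain, from 0.01 to -0.23 in liver and from 0.03 to -0.62 in muscle. The 2 groups did not overlap in 7304 of the 7661, against 77.8% of all features and 33.3% that chance gives for 2 against 2 libraries. Without male gonad 2 the count was 4905, and 12 of the 30 named genes no longer passed (adjusted p 0.058 to 0.55). Without female gonad 1, female gonad 2 and male gonad 1 the numbers no longer past the threshold were 10 (0.05 to 0.16), 7 (0.053 to 0.093) and 2 (0.098 to 0.13). Of the 30, 16 passed with each of the 4 libraries left out, among them the genes named above with the largest differences, Hsd3b7, JAK2, IGFBP5 and vtg1.

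In liver the largest difference among named features was vitellogenin, the yolk precursor that the liver of egg-laying females releases into the blood. The feature vtg1 (TRINITY_DN142608_c2_g1) stood at 17500 ± 10100 FPKM in female and 144 ± 34 in male liver, 432-fold by counts (8.75 ± 0.82, adjusted p = 0.00063). The counts were 126500 and 49551 in female and 340 in each male library. The effective length implied by count and FPKM was 427 and 416 bases in female and 133 and 171 in male liver, so the difference by FPKM is smaller than that by counts. The hemoglobin chain hbaa was also higher in females (1030 ± 852 against 8.41 ± 4.35 FPKM, 7.28 ± 1.64, 0.037), but it did not pass without female liver 1 (0.2), male liver 1 (0.19) or male liver 2 (0.21). Of the 3 features of the blood list 0 passed by edgeR (1 at an unadjusted p below 0.05), or 1 higher adjusted over the list alone. The desaturase SCD, which makes monounsaturated fatty acids, stood at 907 ± 815 against 13.6 ± 5.09 FPKM (6.22 ± 0.7, 0.002). FADD, an adapter of death receptors, was higher in females by 5.51 ± 1.01 (0.015) and GYG1, which primes glycogen synthesis, by 5.16 ± 0.88 (0.011).

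**Figure D1:**
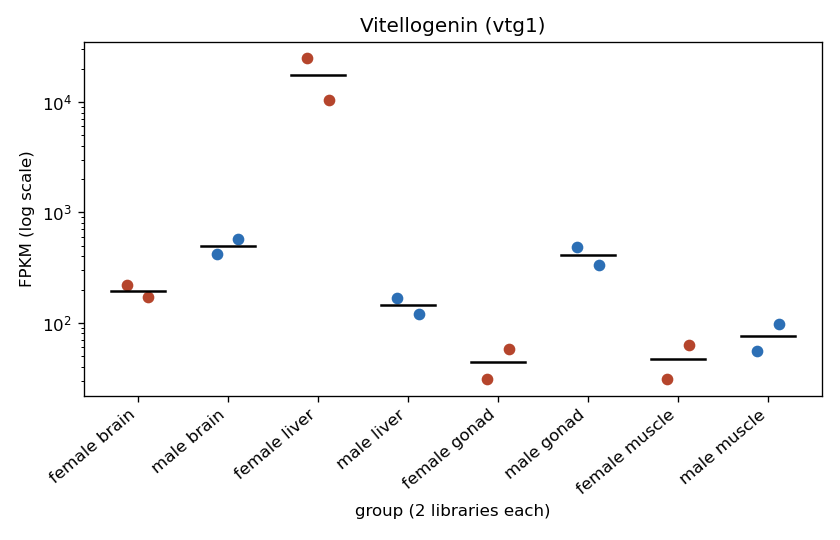
FPKM of vtg1 on a log axis in each of the 16 libraries by tissue, with females in red and males in blue, replicate 1 left and replicate 2 right, and a black line at the mean of each group. Female liver, at a mean of 17500, stood above the other 7 groups, whose means ran from 44.4 in female gonad to 498 in male brain.

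Among the largest differences toward male liver were 3 regulatory genes. Fos, an immediate early transcription factor, stood at 378 ± 350 FPKM in males against 5.01 ± 2.35 in females (-6.13 ± 1.11, adjusted p = 0.014), Gadd45g, a stress response gene, at 730 ± 481 against 17.6 ± 0.375 (-5.2 ± 0.82, 0.0074) and Klf16 at 66.8 ± 51.8 against 1.64 ± 0.276 (-4.84 ± 0.74, 0.0073). SOCS3, an inhibitor of cytokine and growth hormone signalling, was lower in females by -3.79 ± 0.79 (0.029) and was the 1 of 9 growth hormone and IGF features that passed. Of the 4 features of the brain-pituitary-gonad axis 2 were higher in females. CTRL was higher in female liver by 4.25 ± 0.82 (0.019), at 348 ± 133 against 24 ± 28.7 FPKM. These counts were the same adjusted over the list alone. In the hepatocyte list 0 of 12 passed edgeR's test (1 at an unadjusted p below 0.05) and in the steroid list 0 of 12 (2 below 0.05), with 2 higher in males adjusted over the list alone. None of the 6 lists passed as a set in liver (camera adjusted p 0.617 to 0.966).

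In liver 453 features differed, 237 higher in females and 216 in males (116 and 183 scaled by recovered totals, 89 and 146 after quantile normalization). DESeq2 called 1686. A fit on the 4 liver libraries alone called 1 feature, with 2278 at an unadjusted p below 0.05, and none of the 13 named genes passed in it, while the same fit with a block that pairs a female with a male library by number, which no label ties together, called 403. The 2 groups did not overlap in 449 of the 453, against 45.6% of all features and 33.3% by chance. The count rested on single libraries, being 41 without female liver 1, 2764 without female liver 2, 40 without male liver 1 and 162 without male liver 2. Without female liver 1, 11 of the 13 named genes no longer passed (adjusted p 0.078 to 0.29), without male liver 1, 9 (0.052 to 0.3), without male liver 2, 2 (0.21 to 0.25), and without female liver 2, 1 (0.069). Only vtg1 and SCD passed with each of the 4 left out.

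Female brain stood apart in genes encoded by mitochondrial DNA. The features annotated as such took 22 ± 3.91% of the listed counts in female brain and 2.43 ± 0.01% in male brain (n = 2 each). mt-atp6, a subunit of ATP synthase, stood at 24200 ± 7900 against 1140 ± 86.3 FPKM (5.47 ± 1.17, adjusted p = 0.0058). Among nuclear genes MBP, the myelin protein, stood at 1610 ± 340 FPKM in female and 145 ± 15.8 in male brain (3.91 ± 0.53, 0.002), and ATP5J2, a nuclear subunit of ATP synthase, was higher by 4.67 ± 0.89 (0.0041). In male brain CLSTN1, calsyntenin-1 of synaptic membranes, stood at 73.3 ± 23.3 against 1.56 ± 1.14 FPKM (-5.35 ± 0.7, 0.002), ETV5, an ETS transcription factor, at 88.7 ± 52.7 against 3.87 ± 0.495 (-5.09 ± 0.82, 0.0028) and the kinase prkcbb at 72.1 ± 27.3 against 2.08 ± 0.354 (-4.63 ± 0.7, 0.0026).

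**Figure D2:**
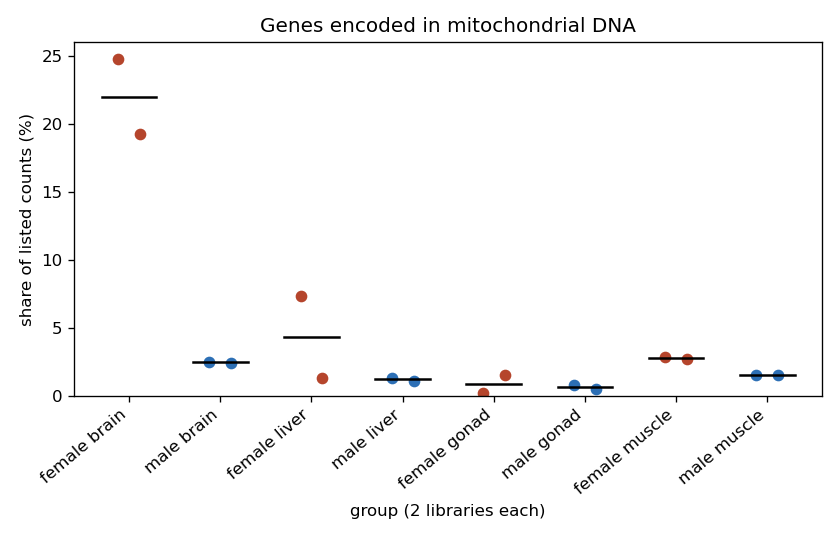
Share of listed counts, in percent from 0, taken by the 11 features annotated as encoded in mitochondrial DNA, in each of the 16 libraries, with females in red and males in blue, replicate 1 left and replicate 2 right, and a black line at the group mean. Both female brain libraries (24.76 and 19.23%) stood above the other 14, of which female liver 1 (7.3%) was the highest.

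Hemoglobin chains and some features of the hepatocyte list were higher in female brain. The chain hbaa, which is outside the blood list, stood at 2590 ± 1910 against 57.2 ± 76.4 FPKM (6.11 ± 1.54, adjusted p = 0.01). The chain hbb1, from that list, was higher by 5.22 ± 1.43 (0.014). Of 3 blood features 1 passed, and 1 was higher and 1 lower adjusted over the list alone. Of the 12 hepatocyte features 6 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 0.0343, but adjusted p = 0.353 with an estimated correlation). They included c3 (3.63 ± 0.95, 0.012), at 23.5 ± 23 FPKM in female brain and 14100 ± 9400 in female liver. Of the 9 growth hormone and IGF features 4 were higher in males and 0 in females, also adjusted over the list alone. SOCS3, IGF2R and Stat5b were among the 4, with -2.72 ± 0.75 (0.014), -1.74 ± 0.49 (0.015) and -1.39 ± 0.46 (0.03). Hsd11b2, which inactivates cortisol, was higher in male brain (-2.96 ± 0.79, 0.013), but its difference was -1.3 without male brain 2.

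The remaining lists were mixed in brain. Of 12 steroid features 2 were higher in females and 1 in males (1 and 1 adjusted over the list alone), of 11 skeletal muscle features 1 and 3 (4 and 3), of 6 testis and sperm features 3 and 1 (3 and 1), and of 4 neuron and glia features 1 and 1 (1 and 1). Of 5 beta-catenin features 2 were higher in females, of 4 brain-pituitary-gonad features 1, and of 4 immune features 0 by edgeR (0 also at an unadjusted p below 0.05). CFAP44, a gene of cilia from the testis and sperm list, was higher in females by counts (2.59 ± 0.45, 0.0035) while its FPKM were 35 ± 1.46 and 32.6 ± 21.1.

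In brain 6471 features differed, 3475 higher in females and 2996 in males (1722 and 4313 scaled by recovered totals). The groups did not overlap in 6153 of these, against 76% of all features and 33.3% by chance. Leaving out 1 library lowered the count to 1774 without female brain 1, 3484 without female brain 2, 3352 without male brain 1 and 2346 without male brain 2. Of the 27 named genes 8 passed in all 4 of these fits, namely hbaa, mt-atp6, ATP5J2, MBP, CFAP44, CLSTN1, ETV5 and prkcbb. Without female brain 1, 18 of the 27 no longer passed (adjusted p 0.057 to 0.72), without female brain 2, 12 (0.056 to 0.15), without male brain 1, 11 (0.056 to 0.29), and without male brain 2, 13 (0.05 to 0.24).

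In muscle the glycolytic enzymes tpi1b and PGK, named for their large differences, and 2 of 11 skeletal muscle features were higher in females. These enzymes stood at 6970 ± 2500 against 344 ± 41.8 FPKM (4.98 ± 0.7, adjusted p = 0.0042) and 2900 ± 1360 against 292 ± 31.4 (4.47 ± 0.72, 0.0076). Without female muscle 2 the difference of PGK was 3.2. As a Gene Ontology term, the glycolytic process did not pass camera's test between the sexes in muscle. The actin acta1b was higher by 2.3 ± 0.55 (0.04), and IGFBP5 stood at 14 ± 2.88 against 2.52 ± 0.636 FPKM (2.82 ± 0.55, 0.017). In male muscle FBXO32, a ubiquitin ligase of muscle atrophy, stood at 416 ± 209 against 5.3 ± 2.84 FPKM (-5.39 ± 0.7, 0.0032) and MROH1 at 27.6 ± 17.3 against 1.96 ± 0.636 (-3.99 ± 0.5, 0.0032). CLU, the secreted chaperone clusterin, and SOCS3 were lower in females by -3.9 ± 0.81 (0.023) and -3.18 ± 0.77 (0.042). Without male muscle 2 these differences were -1.81 and -2.34.

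Of the 11 skeletal muscle features 2 were higher in female muscle, or 4 adjusted over the list alone, and the list rose as a set (camera adjusted p = 0.00205, but adjusted p = 0.157 with an estimated correlation). The 10 most abundant genes took 31.63 ± 3.65% of the listed counts in female and 10.54 ± 5.07% in male muscle. Of the 9 growth hormone and IGF features 1 was higher and 1 lower, or 1 and 2 adjusted over the list alone. Of the 4 neuron and glia features 1, the enolase ENO2, was higher in females (4.29 ± 0.99, 0.035). The ENO3 feature of the same assembled cluster was higher as well (4.04 ± 0.81, 0.019). By edgeR 0 of 12 steroid, 0 of 6 testis and sperm and 0 of 4 brain-pituitary-gonad features passed, with 3, 1 and 1 at an unadjusted p below 0.05. Adjusted over the list alone the counts were 0, 0 and 1, the 1 being higher in females.

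In muscle 481 features differed, 196 higher in females and 285 in males. Scaled by recovered totals 108 and 1990 differed, DESeq2 called 1447, and a fit on the 4 muscle libraries alone called 0 by edgeR, with 2387 at an unadjusted p below 0.05 (231 with the block by number). The groups did not overlap in 468 of the 481, against 49.6% of all features and 33.3% by chance. The count was 37 without female muscle 2 and 189 without female muscle 1, with 10 and 8 of the 13 named genes no longer past the threshold (adjusted p 0.053 to 0.18 and 0.062 to 0.21). Without male muscle 1 and 2, 2 and 6 of them did not pass (0.095 to 0.12 and 0.087 to 0.14). Only tpi1b and MROH1 passed in all 4 of these fits.

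A further comparison averaged the sex difference over brain, liver and muscle. Hemoglobin chains were higher in female soma, hbaa by 6.4 ± 0.9 (adjusted p = 0.0011) and hbb1 by 5.17 ± 0.83 (0.0016). Of the 3 blood features hbb1 was higher and cahz, a carbonic anhydrase, lower (-0.73 ± 0.21, 0.017). Also higher was IGLL5, an immunoglobulin light chain gene (3.31 ± 0.44, 0.00084). IGFBP5 was higher by 1.64 ± 0.3 (0.0025) and vtg1 by 2.92 ± 0.37 (0.00069). Of the 3 tissues behind the average of vtg1 only liver passed (8.75), while brain was at -1.33 ± 0.6 (0.09) and muscle at 1.32 ± 0.61 (0.24). MROH1 was lower in females by -3.73 ± 0.28 (5.5e-05), SLMO2, a mitochondrial lipid transfer protein, by -3.36 ± 0.42 (0.00069), and fos by -3.18 ± 0.56 (0.0021). Fkbp5, a chaperone of steroid receptors that glucocorticoids induce, was lower by -3.34 ± 0.48 (0.0011) and SOCS3 by -3.23 ± 0.44 (0.00097). A lower-expressed feature also named FKBP5 (TRINITY_DN123707_c0_g1) went the other way, higher in female soma by 0.91 ± 0.23 (0.01). In male muscle Fkbp5 stood at 231 ± 173 FPKM and in female muscle at 10.4 ± 2.2, and in male brain at 476 ± 357 against 46 ± 31 in females.

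**Figure D3:**
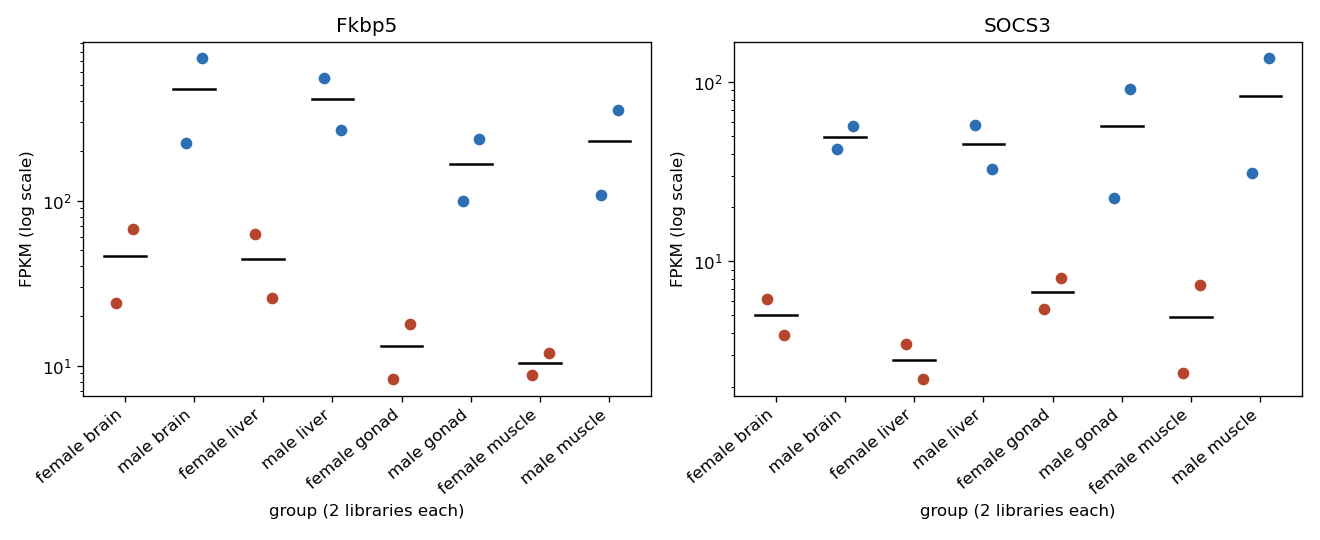
FPKM of Fkbp5 and SOCS3 on log axes in each of the 16 libraries by tissue, with females in red and males in blue, replicate 1 left and replicate 2 right, and a black line at the group mean. Group means of Fkbp5 ran from 10.4 to 46 in females and from 168 to 476 in males, and those of SOCS3 from 2.82 to 6.72 and from 45.3 to 83.6.

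Over the 3 tissues 5856 features differed, 3160 higher in females and 2696 in males (1333 and 5963 scaled by recovered totals). The average rested largely on brain: over liver and muscle alone the count was 1354, and 373 with female liver 1 left aside as well. With 1 mean value per sex and replicate number it was 1673 by limma. Of the 11 skeletal muscle features 5 were higher in females and 0 lower (6 and 2 adjusted over the list alone), and of the 12 hepatocyte features 4 and 0 (4 and 0), with a camera adjusted p of 0.182 for both lists. Of the 9 growth hormone and IGF features 1 was higher and 2 were lower, and of the 4 brain-pituitary-gonad features 2 were higher, the same adjusted over the list alone. Of the 27 named genes 19 passed with each of the 12 libraries left out in turn, and 10 passed in each alternative fit as well: hbaa, hbb1, IGLL5, vtg1, IGFBP5, MROH1, SLMO2, Fkbp5, SOCS3 and fos. Without female liver 1 the count was 3718, and leaving out female brain 1 ended the most of the 27, 7 (0.053 to 0.34).

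Sex calls were set against each other between tissues. Of the features higher in female liver 163 were also higher in female brain, where independent lists would share 50.6, and of those higher in male liver 117 were higher in male brain (39.8). The liver calls behind these counts rested on single libraries, with 41 called in either direction without female liver 1, 40 without male liver 1 and 162 without male liver 2 (2764 without female liver 2). The difference of female liver 1 from female liver 2 correlated across genes with the brain sex difference (r = 0.65). Liver and gonad shared 99 and 116 (55.3 and 51.3), with 49 opposite, and liver and muscle 10 and 12 (2.9 and 3.8), with 3 opposite. Brain and gonad shared 1180 calls higher in females (810.5) and 1268 higher in males (711.9), and 655 features differed in opposite directions. Brain and muscle shared 42 and 48 (41.9 and 52.5), with 61 opposite. Gonad and muscle shared 58 and 39 (45.7 and 67.7), with 174 opposite. The overlaps were compared with these counts and not tested.

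Whether the sex difference itself differed between gonad and soma was tested as an interaction. Among the features with the largest positive interaction, higher in female gonad beyond the somatic difference, were MAP1LC3C (8.11 ± 0.85, adjusted p = 6.3e-05), RND1, a small GTPase (7.7 ± 0.99, 0.00019), slc51a (7.66 ± 0.9, 0.00011) and Thap4 (7.47 ± 0.48, 6.4e-06). Of the named features with a negative interaction vtg1 had the largest (-7.28 ± 0.82, 9.2e-05), being higher in female than male liver and lower in female than male gonad. Hormad1, a protein of meiotic chromosomes, stood at 166 ± 12 FPKM in male and 3.64 ± 2.37 in female gonad (-6.69 ± 0.58, 4.4e-05). JAK2 was -2.02 ± 0.41 (0.0024), while Hsd3b7 was 3.84 ± 0.71 (0.0014).

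In all 5808 features had such an interaction, 2798 positive and 3010 negative (1972 and 3179 scaled by recovered totals). The count was 3653 without female gonad 1 and 3781 without male gonad 2. CD74 (-4.53 ± 1.17, 0.009) did not pass without either (0.069 and 0.11). Leaving out female gonad 1 ended the most of the 26 named genes, 10 (0.05 to 0.17), and 16 of them passed with each of the 16 libraries left out, among them the other genes named here. Of the 4 brain-pituitary-gonad features 3 were negative and 0 positive, of the 9 growth hormone and IGF features 4 and 0, and of the 12 hepatocyte features 5 and 2, each the same adjusted over the list alone. Of the 12 steroid features 2 were negative and 3 positive, or 2 and 4 adjusted over the list alone.

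A second interaction set liver against brain and muscle, since the liver of female fish makes yolk precursors. The sex difference of vtg1 was larger in liver by 8.75 ± 0.87 (adjusted p = 0.0016) and that of SCD by 4.78 ± 0.74 (0.022). In the other direction were id3-a, an inhibitor of basic helix-loop-helix factors, at 31.2 ± 15.1 in female and 269 ± 23.8 in male liver (-3.19 ± 0.42, 0.0084), and CIART, a repressor of the circadian clock (-3.91 ± 0.64, 0.029).

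In all 19 features passed, 11 positive and 8 negative (14 and 4 scaled by recovered totals, 11 and 5 by median-of-ratios scaling), and DESeq2 called 219, 97 positive and 122 negative. The hepatocyte list was negative as a set, with 0 of 12 features past edgeR's threshold, also adjusted over the list alone, and 2 at an unadjusted p below 0.05 (camera adjusted p = 0.000456, but adjusted p = 0.366 with an estimated correlation). The count was 8 without female brain 2 or female muscle 2, 9 without female brain 1 or male brain 2, 11 without male liver 1, 12 without male brain 1 and 35 without female liver 2. Of the 10 named genes only vtg1 and id3-a passed in all 12 of these fits. SCD did not pass without male liver 1 (0.18), male liver 2 (0.073), either male brain library (0.053 and 0.061), female brain 2 (0.076) or female muscle 2 (0.062). CIART did not pass in 9 of the 12 (0.06 to 0.11).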

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

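The tests of abundant brain transcripts, shared handling or batch, time of day, stress before sampling and both tests of vitellogenin were chosen only after the results they concern were seen. The tests of gene length, of 27 brain-enriched features, of scaling and of other splits of the libraries were written before theirs.

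Some sex differences differed between tissues by a direct test, an interaction in edgeR. Between gonad and soma 5808 features had such a difference, among them vtg1 (-7.28 ± 0.82, adjusted p = 9.2e-05). Between liver and the mean of brain and muscle there were 19, among them vtg1 (8.75 ± 0.87, 0.0016) and SCD (4.78 ± 0.74, 0.022). The sex differences in liver (SCD 6.22 ± 0.7) and gonad (vtg1 -4.37 ± 0.69) had the signs of these interactions. Leaving out single libraries moved the first count to 3653 (female gonad 1) and 3781 (male gonad 2). The second moved to 8 without female brain 2 or female muscle 2, 9 without female brain 1 or male brain 2, 11 without male liver 1, 12 without male brain 1 and 35 without female liver 2. SCD did not pass without female brain 2, female muscle 2 or any of the male brain and male liver libraries (0.053 to 0.18). With 2 libraries in each group, no test within a group could show a library far from the others. Across groups, female liver 2 correlated with the male liver libraries at 0.904 and 0.905 (log2 values), female liver 1 at 0.785 and 0.744, and female liver 1 with the female brain libraries at 0.755 and 0.734.

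Other splits of the libraries were tried, 100 for each result with the real one included. For the sex difference averaged over brain, liver and muscle, 1 of 100 splits, the real one, gave as many calls (5856, highest other 5512), so chance can be excluded only if the libraries of different tissues are independent. If those of the same sex and number came from 1 fish, the fish are too few for such a count of splits, and a mean per fish gave 1673 calls. The 31 drawn splits that kept the brain libraries in their sexes reached 5512, and the highest among the others was 3. Those others mix the sexes of brain, which puts the brain difference into the spread that all groups share. That lowers the calls whatever liver and muscle hold, so the drop to 3 cannot show which tissue the calls come from. For the features enriched in brain, liver, gonad and muscle, 1 of 100 splits, the real one, gave as many (288, 508, 389 and 304, with highest others 39, 155, 119 and 4). The other splits put libraries of different tissues into 1 group, which widens the spread and shrinks the tissue differences. The real split was thus favoured in advance, and its rank adds no support to these features.

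Female liver 1 departed from female liver 2 along the sex difference of brain: across 16270 genes, which are not independent replicates, the difference between the 2 libraries correlated with the brain difference at r = 0.65, against -0.39 to 0.43 for the other 5 replicate pairs. After the trend with gene length was removed r was 0.64, which argues against gene length as the whole cause. Brain RNA in female liver 1 would raise brain transcripts of both kinds: the 27 brain-enriched features higher in male brain had a median of -0.29 (SE 0.34), which alone did not decide, and all 288 had a median of 0.83. The 20 most abundant brain-enriched features lay above female liver 2 for 17 of 20, by a median of 0.64% of their female brain level (SE 1.12%) where the mitochondrial share would need 29.1%, and MBP was at 1.28 and 2.32 FPKM in female liver 1 and 2. This argues against brain RNA as the cause, though the bound was moved from each of the 20 features to their median after 1 feature had reached 14.7%. Handling or a batch shared by the female brain libraries and female liver 1 (r = 0.65) stays open because the labels name no batch, and it cannot be told apart from a biological difference between the fish, which was not tested.

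Some glucocorticoid-response genes were higher in male tissues: for 8 genes (FKBP5, DDIT4, TSC22D3, SGK1, CEBPD, PER1, SOCS3 and FBXO32) 25 of 32 gene and tissue pairs were higher in males, 17 past edgeR's threshold, where 49.3% of the pairs of all features were higher in males and 11.3% past the threshold. The list was written after most values were seen, so these counts do not test the pattern: 4 of the genes were already named for it, the other 4 gave 12 of 16 pairs (6 past the threshold), and a second FKBP5 feature was higher in female gonad (1.77 ± 0.38, adjusted p = 0.0023). The median log2 sex difference nearest 0 over 3 scalings was -2, by median-of-ratios (-2.02 by TMM, -2.7 by recovered totals). The median of all genes was 0.02, 0.04 and -0.48 under them, so the 3 differ too little to bring -2 to 0. This argues against the choice among these 3 scalings as the cause and does not address another scaling. Time of day at sampling stays open: 19 of 24 pairs of clock output genes (PER1, PER2, NR1D1, NR1D2, CIART and BHLHE41) were higher in males. PER1 is also among the 8 genes above, so the 19 and the 25 pairs are not separate evidence. ARNTL, an activator of the clock, had a lower mean in males in 2 tissues and a higher one in 2. Only brain was past edgeR's threshold (-3.1 ± 0.45, 0.0023, higher in males), and another ARNTL feature was past it in muscle the other way (2.14 ± 0.49, 0.033). Stress or handling of the fish before sampling may also account for the 25 pairs, and it cannot be told apart from sex, since the labels do not say how each sex was handled or when, and a sex difference in glucocorticoid signalling was not tested.

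Vitellogenin counts were present in male liver, at 340 in each library. Each gene in the table stood at 0.31 FPKM or more in each library. Some vtg1 counts in male liver were therefore given by the choice of genes, and their presence alone is not a finding. Reads carried over from the female liver libraries would have the same effective length. The largest effective length in male liver was instead 0.41 of the smallest in female liver, which argues against carry-over as the source of all these counts. It cannot exclude carry-over of a part, since other reads on a short isoform would lower the effective length of a mixture. An even leak of reads into every library would give each about the same share of vtg1 counts in its recovered total. The lowest library, in female gonad, held 0.09 of the share of the lower male liver library. This argues against an even leak and does not address an uneven one. Carry-over of a part of the counts and an uneven leak stay open. Expression of vtg1 in male liver, or reads of a related gene, remain as untested hypotheses.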

How the results depend on the processing

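The alternatives with DESeq2, limma on log2(FPKM + 1), recovered totals, the length trend removed, mitochondrial genes removed, both female brain libraries and female liver 1 set aside, and liver and muscle alone were chosen after the data were seen. The cause was not tested for any change given here, except where fewer libraries were used. With no filter in place of the chosen one no gene is added, so that alternative gave no separate value. Depth limits the features with few counts, 724 of which had under 3 in a library.

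Of the 183 results of named genes, some genes being named in several comparisons, 183 passed under DESeq2 and 183 under the stricter filter of 5 FPKM, 177 under median-of-ratios scaling and 160 under recovered totals, and none changed sign there. With limma on log2(FPKM + 1) 148 passed, 34 did not and 1 reversed. The reversed gene was CFAP44 in the somatic average: -0.22 with limma on log2(FPKM + 1), -0.25 with log2(FPKM + 0.1), -0.22 with array weights, -0.22 with the replicate block and -0.22 with a mean per fish. In the average over liver and muscle leaving aside female liver 1, lamtor3 reversed (-0.16).

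Enriched features numbered 931 in brain, 1256 in liver, 1731 in gonad and 931 in muscle with a log2 difference of at least 1. Met within each sex separately, the rule gave 105, 266, 98 and 148. For liver, gonad and muscle they were 222, 1554 and 156 under recovered totals, 190, 1261 and 130 with limma on log2(FPKM + 1), 203, 1543 and 143 with log2(FPKM + 0.1), and 185, 1261 and 128 with array weights. The sex difference in liver and in muscle gave 299 and 2098 calls under recovered totals, 1686 and 1447 with DESeq2, 199 and 1437 with limma on log2(FPKM + 1), 209 and 1485 with log2(FPKM + 0.1), 235 and 302 after quantile normalization and 73 and 237 with array weights. A fit on the 4 libraries of the tissue gave 1 in liver and 0 in muscle by edgeR (2278 and 2387 at an unadjusted p below 0.05).

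The liver interaction gave 219 with DESeq2, 12 with log2(FPKM + 0.1), 12 after quantile normalization and 5 with array weights. The gonad and soma interaction gave 3865 after quantile normalization. The somatic average gave 1673 with a mean per fish, 1354 over liver and muscle, and 373 leaving aside female liver 1 too. Of 15 list tests 2 passed with the correlation estimated. With the length trend removed or without mitochondrial genes, each sex comparison stayed within 1.5 times its count.

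If libraries of the same sex and number came from 1 fish, the replicate block pairs them. With it (duplicateCorrelation, limma, consensus correlation 0.102) there were 222 calls in liver and 1480 in muscle, and 191 features enriched in liver, 1261 in gonad and 131 in muscle. In the fit on 4 libraries a fixed block can pair only a female with a male library of the same number, which no label ties together, and it gave 231 in muscle and 403 in liver. The pairing is not established: correlations between tissues by number ran from -0.31 to 0.23 in females and 0.19 to 0.59 in males.

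With each library left out in turn, the lone library of a group being assumed to vary like the other groups, the sex difference ran from 1774 to 3484 in brain, 40 to 2764 in liver, 4905 to 6050 in gonad, 37 to 410 in muscle and 3718 to 7431 in the somatic average. The gonad and soma interaction ran from 3653 to 6342 and the liver interaction from 8 to 35. Enriched features ran from 268 to 336 in brain, 463 to 535 in liver, 333 to 421 in gonad and 270 to 354 in muscle, and list tests from 11 to 17. All 37 named enriched genes passed in each of these fits. The libraries behind the lowest counts were female brain 1 (1774), male liver 1 (40), male gonad 2 (4905), female muscle 2 (37), female liver 1 (3718), female gonad 1 (3653), and female brain 2 or female muscle 2 (8). Counts moved more than 1.5 times also without female brain 2 (3484), male brain 1 (3352) and male brain 2 (2346) in brain, female liver 1 (41), female liver 2 (2764) and male liver 2 (162) in liver, female muscle 1 (189) in muscle, and male gonad 2 (3781) in the gonad and soma interaction.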

Other observations

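The tests of Gene Ontology terms were chosen after the data were seen, and the term sizes were widened from 300 to 500 genes after a first run. Directions are female minus male or the named tissue minus the others, with the median log2 difference and the camera adjusted p at the preset correlation. With the correlation estimated and adjusted over all 438 terms, none of the terms given here passed (adjusted p = 0.25 to 1 with an estimated correlation), so the calls rest on the preset correlation, and the counts of genes past edgeR's threshold are given as such.

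Between gonad and the other tissues, of 218 DNA repair genes 114 were higher and 40 lower (median 0.64, adjusted p = 0.00068, but adjusted p = 0.25 with an estimated correlation), of 58 rRNA processing genes 32 and 7 (1.03, 0.0024, but adjusted p = 0.38 with an estimated correlation), and of 35 genes of mitotic nuclear division 19 and 4 (0.81, 0.0018, but adjusted p = 0.43 with an estimated correlation). Of 37 genes of the glycolytic process 23 were lower in gonad and 6 higher (-1.43, 0.01, but adjusted p = 0.38 with an estimated correlation). In liver 11 of 24 tryptophan metabolism genes were higher and 0 lower (0.43, 3.8e-05, but adjusted p = 0.92 with an estimated correlation). In muscle 9 of 13 collagen trimer genes were higher and 1 lower (2.88, 8.3e-05, but adjusted p = 1 with an estimated correlation).

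Between the sexes in muscle, the 26 genes of the proteasome core complex had a median of -1.33 (adjusted p = 2e-13, but adjusted p = 0.97 with an estimated correlation), with 5 past edgeR's threshold, all higher in males. In the comparison of tissues 22 of the 26 were higher in muscle and 0 lower. In brain 25 of 56 genes of protein deubiquitination were higher in males and 2 in females (-1.05, 0.0057, but adjusted p = 0.84 with an estimated correlation), and 13 of 26 genes of the histone acetyltransferase complex were higher in males and 0 in females (-1.48, 0.013, but adjusted p = 0.84 with an estimated correlation). In gonad 11 of 17 genes of peptidyl-prolyl isomerization were higher in females and 0 in males (1.24, 0.05 rounded up from below the threshold, but adjusted p = 0.91 with an estimated correlation).

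Mitochondrial genes took 7.3% of the listed counts in female liver 1 and 1.26% in female liver 2.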
